A study of Mus musculus with 6 samples.

How the data were processed

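Polyadenylated RNA of mouse CD8+ T cells carrying the OT-I receptor, taken from spleen and lymph nodes, was measured in 6 libraries. They form 3 groups of 2: cells 4 days after the N4 peptide, cells 4 days after the T4 peptide, both with antibodies to OX40 and 4-1BB, and naive cells. RNA was extracted with the miRNeasy Micro kit and libraries were made with the SMARTer ultra-low input poly(A) kit, per the labels' protocols. The submitters' processing notes name the genome build mm39 and the tools STAR 2.7.1a, SAMtools 1.9, StringTie 2.1.0, R 4.0.5 and DESeq2 1.30.1, with no role or order given. The annotation release, strand setting, sorting gate and sequencing depth in reads are not given in the sources used here. The kit named does not mark strand, so reads of overlapping genes on opposite strands cannot be assigned with certainty.

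The authors deposited estimated counts per gene (55414 genes) and per transcript (142435 transcripts), not normalized, as whole numbers, so that no rounding was needed. Both tables have the same totals in each library. The library totals run from 269033066 to 335968843 estimated counts. If these estimates were derived from coverage, their scale depends on an assumed read length that is not given in the sources used here, so the totals are not taken as numbers of reads. Intervals and floors cover counting error only, and they are too narrow if the estimates exceed the reads. No column of per-sample values was left over. A symbol was found for 52081 gene identifiers (94%) and a GENCODE M21 transcript model for 138292 transcripts (97.1%). Those models lie on GRCm38, a different build from the one named for the deposited values, so they served for symbols, transcript types, lengths, GC content and exon structure, and all coordinates are GRCm38 coordinates.

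Replicates were compared before averaging. The chi-square per degree of freedom between the 2 libraries of a group was 368.3 for N4, 130.6 for T4 and 2380.6 for naive, far above sampling noise, so none was treated as a duplicate. The labels used here give no sex of the mice and do not say that replicates came from separate mice. The p-values then measure only the spread between these libraries, which may be technical.

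Gene changes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: TMM scaling, filterByExpr by group (23003 genes kept), and the quasi-likelihood test on group means over all 6 libraries, which share one estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.67 and the prior degrees of freedom 3.1, beside 3 residual ones. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values are counts scaled by library total and TMM factor and are given as mean ± SD with n = 2. A fold against a group at 0 in all its libraries is given as a lower bound from a floor of 3 counts per library.

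The tests, their alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. The lists are 18 pathway lists and 8 lists of markers of other cells. The rule names Tra2b, then for each comparison the 6 higher and 6 lower genes of largest fold change among those past the threshold, with a mean log2 CPM of at least 3, non-overlapping CPM values and a symbol that is not a predicted gene, pseudogene, receptor segment, ribosomal or mitochondrial gene, and then 2 to 4 members of each list described, by smallest p. The rule named 210 genes. The exons of 58 of them overlap those of another gene on either strand, and those of 24 overlap a protein-coding gene, which makes their values less certain. Aldoa has 2 identifiers, so the 19 glycolysis symbols gave 20 measured entries. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. With an estimated correlation, camera also uses only the 3 residual degrees of freedom, which limits its power.

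Transcript usage was tested with edgeR's diffSpliceDGE on 42444 transcripts of 10393 genes, with Simes p-values per gene. The share of Tra2b counts in transcripts covering its poison exon was computed per library, as was, for splicing factors of the SR and TRA2 family, the share in transcripts annotated as targets of nonsense-mediated decay. For 2 libraries against 2 an exact permutation test cannot go below p = 0.33, so no permutation p is given. Agreement of the responses to both peptides was set beside 20 simulations of unchanged groups against the same naive libraries.

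The procedures were tested on simulated counts for 23003 genes with 200 changed genes. Of the genes changed 2-fold, 4-fold and 16-fold, the test found 0%, 28.4% and 97% in N4 against naive (10 false calls), 1.5%, 25.4% and 95.5% in T4 against naive (5 false calls) and 1.5%, 37.3% and 95.5% in N4 against T4 (8 false calls). For transcript usage, the main transcript of 200 genes was set to the level of the second transcript divided by 4. The remainder went to the second transcript, so the main one fell 4-fold or more. Of these switches 21.5%, 22% and 16.5% were found in these comparisons, with 2, 6 and 5 false calls. Recovery of an exact 4-fold change in usage was not simulated. Fold changes of 2 are therefore largely out of reach with these libraries.

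Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter and a stricter filter (1 CPM in all libraries of a group and 50 counts), only the 2 groups compared, the replicate number as a block, a minimum fold change of 1.5, each library left out in turn, other list and usage tests, and shares divided by transcript length. Scaling by library size alone, corrections for transcript length and GC content (splines with 5 degrees of freedom), and counts divided by 4 were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.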

Results

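CD8+ T cells bearing the OT-I receptor, which recognises a fragment of ovalbumin, were profiled 4 days after stimulation with the N4 peptide, the ovalbumin fragment itself, or with T4, a variant of it with lower potency for the same receptor. Both peptides came with antibodies that engage the costimulatory receptors OX40 and 4-1BB, and naive OT-I cells served as the unstimulated reference. Each of the 3 groups held 2 libraries. The libraries held 269033066 and 319310732 estimated counts for N4, 296931714 and 301781295 for T4, and 335968843 and 299807223 for naive. Genes with a count above 0 numbered 21579 and 21317 in N4, 27147 and 27098 in T4, and 24280 and 23871 in naive libraries. Across genes, log2 CPM values correlated at 0.929 between the N4 libraries, 0.952 between the T4 libraries and 0.915 between the naive libraries. The principal component with the most variance (45.6%) set N4 apart from both other groups, and the next (22.5%) set T4 apart from both other groups. Xist, an RNA of the inactive X chromosome of female cells, stood at 0.05 and 7.09 CPM in N4, 0.03 and 0.05 in T4 and 20.3 and 31.5 in naive libraries. Ddx3y, a gene of the Y chromosome, stood at 7.68 and 6.03, 7.27 and 4.89, and 4.41 and 5.67 CPM.

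The series concerns the ultraconserved poison exon of Tra2b, a splicing activator of the SR family, and asks how antigen receptor stimulation bears on it. A poison exon carries a premature stop codon, so that transcripts including it are degraded by nonsense-mediated decay rather than translated. Tra2b (ENSMUSG00000022858.17) lies on the minus strand of chromosome 16 at 22244549 to 22266005 in GRCm38. Its poison exon spans 22258986 to 22259261 (276 bp) and is exon 2 of the decay transcript Tra2b-206. It lies in the intron between the exon at 22265741 to 22266005 and the exon at 22254984 to 22255117 of the coding transcript Tra2b-204.

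Transcripts covering the poison exon made up 30.3% ± 2.4 of the Tra2b counts in N4 cells, 38.3% ± 0.2 in naive cells and 44.4% ± 2.8 in T4 cells (SD, n = 2). Per library the shares were 32% and 28.7% in N4 (exact 95% binomial intervals 31.4 to 32.6 and 28.1 to 29.2), 42.4% and 46.4% in T4 (41.9 to 42.9 and 45.9 to 47) and 38.5% and 38.2% in naive (38 to 39 and 37.5 to 38.9). The share in N4 lay 14.1 points below that in T4, with a combined SD of 3.7 points, and 8 points below that in naive cells, with a combined SD of 2.4. The share in T4 lay 6.1 points above naive, with a combined SD of 2.9. The groups did not overlap, and the nearest libraries of N4 and T4 were 10.4 points apart. Other measures of RNA composition moved too: retained intron transcripts held 3.22% ± 0.05 of the counts of protein-coding genes in N4, 4.31% ± 0.07 in T4 and 3.98% ± 0.49 in naive libraries. Decay transcripts of all protein-coding genes held 2.16% and 1.62% of the same counts in N4, 3.26% and 1.62% in T4, and 1.77% and 1.3% in naive libraries, so their groups overlapped and naive had the lowest mean, unlike the order for Tra2b. Malat1, a nuclear RNA, held 0.021% of all counts in both N4 libraries, 0.133% and 0.136% in T4, and 0.129% and 0.069% in naive libraries. The coding transcript Tra2b-204 took the converse shares: 66.6% ± 2.3 in N4, 52.6% ± 3.7 in T4 and 59.1% ± 0.3 in naive cells.

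In TMM-scaled CPM, the poison exon transcripts stood at 37.6 ± 0.3 in N4, 41.6 ± 1.7 in T4 and 31.5 ± 3.2 in naive cells, while Tra2b-204 stood at 82.8 ± 10 in N4, 49.3 ± 4.7 in T4 and 48.5 ± 4.8 in naive cells. The whole gene measured 124.2 ± 10.8, 93.6 ± 2.26 and 82 ± 7.79 CPM. Its log2 fold change was 0.60 (SE 0.22, edgeR adjusted p = 0.13) in N4 against naive, 0.19 (SE 0.22, adjusted p = 0.79) in T4 against naive and 0.41 (SE 0.22, adjusted p = 0.28) in N4 against T4, turning to -0.057 with a GC correction and to -0.458 under library size scaling. The gene passed the threshold in none of these. Relative use of Tra2b-206 did not pass the transcript test either: its log2 relative change was -0.21, 0.18 and -0.39 in the same order, each with an adjusted p = 1 from diffSpliceDGE. Dividing counts by transcript length raised the shares to 48.2% ± 2 in N4, 62.5% ± 2.8 in T4 and 56.9% in both naive libraries, in the same order. An exact permutation test of 2 libraries against 2 cannot go below p = 0.33.

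**Figure D1:**
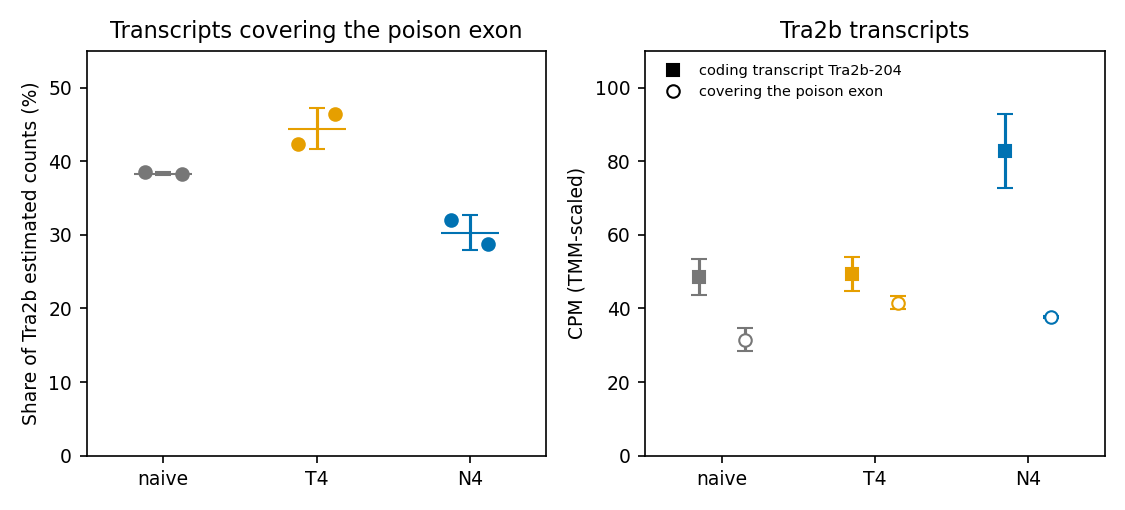
Share of Tra2b estimated counts in transcripts covering the poison exon (left, %), per group, with points for libraries and bars for mean and SD (n = 2). The right panel gives CPM of the coding transcript Tra2b-204 and of the poison exon transcripts, with symbols for group means and bars for SD (n = 2). The share is lowest in N4 (30.3%) and highest in T4 (44.4%), and Tra2b-204 is at 82.8 TMM-scaled CPM in N4 against 49.3 in T4, an order that rests on the scaling, since the whole gene turns to a log2 fold change of -0.458 under library size scaling.

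Other splicing factors of the SR and TRA2 family with annotated decay transcripts numbered 11 with Tra2b. From T4 to N4 the share of such transcripts was lower for 9 of them, Tra2b included, and higher for 2 (counting Srsf5 as lower, whose share rounds to 0 in each group), with a median difference of -1.4 points (SD over library pairs 0.51). Over 1626 genes with decay transcripts and a mean log2 CPM of at least 3, the share was lower in N4 than in T4 for 55.4%. It was lower in N4 than in naive libraries for 49.8% of them. Srsf7 stood at 7.8% ± 2.8 in N4, 16.3% ± 2.3 in T4 and 17.1% ± 11.4 in naive cells. In N4 against naive the median difference was -1.19 points (SD 0.92, 3 genes higher and 8 lower, Srsf5 among the latter), and in T4 against naive -0.33 points (SD 0.48, 5 higher, Srsf5 among them, and 6 lower). The latter median turned to 0.03 without T4 replicate 1 and to 0.02 without naive replicate 1. Tra2a, the closest relative of Tra2b, went the other way from Tra2b in N4 against naive, with 11.7% ± 1.2 in N4, 13.1% ± 3.4 in T4 and 3.3% ± 0.4 in naive cells. Srsf3 varied by as much within groups as between them (14% ± 17, 18.2% ± 16.6 and 16.6% ± 13). Shares divided by transcript length gave medians of -2.84 points in N4 against naive and -3.32 points in N4 against T4. With each library left out in turn, the median in N4 against T4 ranged from -1.8 to -0.22 points.

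The comparison of N4 with naive cells asks what differed 4 days after the potent peptide and the antibodies. Naive cells were unstimulated, so a difference from them cannot be assigned to the peptide alone. Cell division genes rose together: 27 of 35 cell cycle genes rose and none fell (34 and 0 adjusted over the list alone), with a median log2 fold change of 2.18 (camera adjusted p = 1.9e-16, and adjusted p = 0.19 with an estimated correlation). Mki67, a marker of cycling cells, went from 4.49 ± 0.177 to 33.7 ± 1.85 CPM (SD, n = 2, log2 fold change 2.91, SE 0.25, edgeR adjusted p = 0.0071). The mitotic motor gene Kif11 rose from 2.12 ± 0.413 to 19.6 ± 1.04 CPM. Among 20 cytotoxic effector genes 6 rose and 1 fell (6 and 3 adjusted over the list alone). Gzmb, which encodes the killing protease granzyme B, rose 10-fold to 454.9 ± 45.1 CPM (adjusted p = 0.028). Serpinb9, its inhibitor, rose 17.4-fold to 152.2 ± 13.3 CPM (adjusted p = 0.0071). Ifng, which encodes interferon gamma, rose to 78.2 ± 54.9 CPM from 4.48 ± 1.98 (adjusted p = 0.017). Of 24 naive and memory genes 10 fell and none rose (14 and 0 adjusted over the list alone), with a median of -1.21 (camera adjusted p = 0.00047, and adjusted p = 0.4 with an estimated correlation). Lef1 and Bcl2, a transcription factor and a survival factor of resting T cells, fell, with log2 fold changes of -2.38 and -2.08 (adjusted p = 0.018 and 0.014).

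Some genes of RNA splicing and metabolism also rose, a minority in each list. Of 24 hnRNP and PTB splicing factors 7 rose (12 adjusted over the list alone) and none fell, with a median of 0.76 (camera adjusted p = 5.2e-05, and adjusted p = 0.2 with an estimated correlation). Hnrnpd, an RNA-binding protein, rose by 2.16 (SE 0.28, edgeR adjusted p = 0.012) to 135.8 ± 8.08 CPM. Of 13 SR and TRA2 splicing factors 2 rose, Srsf3 by 1.74 (SE 0.30, adjusted p = 0.022) and Srsf2 by 1.52 (SE 0.26, adjusted p = 0.023), and none fell (4 and 0 adjusted over the list alone). The list's median was 0.61 (camera adjusted p = 0.011, and adjusted p = 0.2 with an estimated correlation), and a GC correction lowered it to 0.33 and ended its call (adjusted p = 0.061). Under library size scaling the medians were 0.02 for the SR and TRA2 list, 0.22 for the hnRNP and PTB list, 0.12 for glycolysis, 0.45 for sterol and fatty acid synthesis and 0.21 for the cytotoxic list. In sterol and fatty acid synthesis 4 of 18 genes rose (6 adjusted over the list alone), among them Idi1 of the isoprenoid pathway, 8.59-fold to 53.9 ± 8.37 CPM (median 0.99, camera adjusted p = 0.0022, and adjusted p = 0.19 with an estimated correlation). Of 20 glycolysis entries 3 rose (3 adjusted over the list alone), with Pgk1 up 3.71-fold and Hk2 4.52-fold (median 0.71, camera adjusted p = 0.0098, and adjusted p = 0.4 with an estimated correlation). Of 29 oxidative phosphorylation genes 1 rose, Uqcrfs1 (0 adjusted over the list alone), with a median of 0.61 that turned to -0.07 under library size scaling (camera adjusted p = 0.0015, and adjusted p = 0.3 with an estimated correlation). The cytotoxic list had a median of 0.68 (camera adjusted p = 0.015, and adjusted p = 0.5 with an estimated correlation). Its call ended without naive replicate 1 (adjusted p = 0.18) and with fry (adjusted p = 0.093), and the glycolysis call ended without N4 replicate 1 (0.064), without naive replicate 2 (0.072) and with fry (0.09).

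Among called genes that pass the naming rule's filters (a mean log2 CPM of at least 3 among them), the largest increases in N4 against naive were those of Nebl, an actin-binding protein gene, 84.4-fold to 39.9 ± 6.14 CPM, and Mt3, a metallothionein gene, 79.7-fold to 79.2 ± 27.7 CPM. Zbtb32, a transcriptional repressor gene of activated lymphocytes, rose 51.6-fold to 46.3 ± 11.9 CPM. They were followed by Ctla4, the inhibitory receptor gene, at 41.3-fold, Upk1a at 32.9-fold and Slamf1, a lymphocyte surface receptor gene, at 32.2-fold (edgeR adjusted p = 0.0071 to 0.021). Among the called genes that pass the naming rule's filters, the largest decreases had log2 fold changes of -12.27 for Lrg1, -10.81 for Fcna, -9.83 for Fpr1, -9.71 for Stfa2l1, -9.30 for C1qc, a complement gene of macrophages, and -9.24 for Pilrb1 (adjusted p = 0.0071 to 0.026). Their N4 means lay near 0, from 0.0098 CPM for Lrg1 to 0.305 for C1qc, so the sizes of these folds are uncertain. The naive libraries differed widely for some, with 24.4 ± 25.1 CPM for Stfa2l1 and 69 ± 54.7 for Fcna, against 32.5 ± 3.75 for Pilrb1. Stfa2l1 and Pilrb1 have close paralogs that can share reads. Summed macrophage and monocyte markers stood at 2468.6 ± 310.4 CPM in naive and 19.2 ± 2.1 in N4 libraries, and neutrophil markers were lower in N4 too. These decreases therefore cannot be assigned to a change within CD8 T cells.

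Among the other pathway lists, none passed the camera test in N4 against naive. Counts in parentheses are those adjusted over the list alone. Of 17 inhibitory receptor genes 5 rose and 1 fell (8 and 2, median 0.87, camera adjusted p = 0.077). Of 20 type I interferon genes 1 rose and 5 fell (1 and 8, median -0.65, adjusted p = 0.052). Of 18 effector differentiation genes 2 rose and 4 fell (8 and 4, median 0.63, mean -0.09, adjusted p = 0.26). Of 13 costimulatory receptor genes 3 rose and 2 fell (4 and 2, median -0.13, mean 0.21, adjusted p = 0.63), with Icos up 3.57-fold to 92 ± 18.9 CPM and Tnfrsf4, which encodes OX40, up by 2.61 to 7.17 ± 4.17 CPM. Of 17 cytokine receptor and signalling genes 2 rose and 5 fell (3 and 6, median 0.06, adjusted p = 0.93). Il2ra, the high-affinity interleukin 2 receptor chain, rose 28.5-fold to 20.3 ± 2.17 CPM. Socs3, a feedback inhibitor of cytokine signalling, fell by 3.03 on the log2 scale. Of 25 antigen receptor response genes 2 rose and 3 fell (3 and 3, median -0.47, mean 0.08, adjusted p = 0.93). Of 15 homing genes 3 rose and 2 fell (4 and 2, median -0.23, with the test's direction up, adjusted p = 0.64). The integrin genes Itgb1 and Itga4 rose 7.6-fold and 4.94-fold, and the gut homing receptor gene Ccr9 had a log2 fold change of -4.65. Of 15 nonsense-mediated decay genes 1 rose, Magoh (0 and 0, median 0.18, adjusted p = 0.17). Of 22 ribosome biogenesis genes 1 rose, Nop58 (0 and 0, median 0.27, adjusted p = 0.25). Of 8 SR protein kinases 1 fell, Clk1 (0 and 1, median -0.25, adjusted p = 0.69).

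Markers of other cells fell with these groups. Summed macrophage and monocyte markers stood at 19.2 ± 2.1 CPM in N4 and 2468.6 ± 310.4 CPM in naive cells, and 11 of 12 fell (12 adjusted over the list alone, median -7.36, camera adjusted p = 4.1e-09, and adjusted p = 0.18 with an estimated correlation). Summed neutrophil markers stood at 43.1 ± 4.9 CPM in N4, at 2394 CPM in naive replicate 1 and at 24753.4 CPM in naive replicate 2, and 6 of 8 fell (8 adjusted over the list alone, median -8.09, adjusted p = 5.4e-05, and adjusted p = 0.29 with an estimated correlation). Of 11 B cell markers 8 fell (8 adjusted over the list alone, median -4.79, or -2.62 with genes at 0 set at their bound, adjusted p = 3.3e-05, and adjusted p = 0.19 with an estimated correlation). Dendritic cell markers fell for 7 of 10 genes (7 adjusted over the list alone, median -4.36, or -4.17 with bounds, adjusted p = 5.4e-05, and adjusted p = 0.19 with an estimated correlation), with H2-Aa, a class II antigen presentation gene, at 33.7 ± 4.56 CPM in N4 and 686.3 ± 57.8 in naive cells. Red cell markers fell for 6 of 7 (7 adjusted over the list alone, median -4.14, adjusted p = 5.1e-05, and adjusted p = 0.3 with an estimated correlation), from 6339.8 ± 4090.8 to 391.3 ± 44.5 CPM in sum. Their globin genes are near-identical copies. Natural killer cell markers fell for 4 of 6 (5 adjusted over the list alone, median -4.99, adjusted p = 0.00026, and adjusted p = 0.19 with an estimated correlation). CD4 and regulatory T cell markers had 0 calls of 4 (0 adjusted over the list alone, median -0.5, adjusted p = 0.68). Stromal and endothelial markers had 1 call of 8, downward (3 adjusted over the list alone, median -0.98, adjusted p = 0.05).

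In all, 2772 of 23003 genes passed the threshold in N4 against naive, 1120 higher and 1652 lower (7080 at an unadjusted p under 0.05). Under library size scaling 695 were higher and 1777 lower. That scaling shifts the median log2 fold change of all genes to -0.65 in N4 against naive, to 0.30 in T4 against naive and to -1.05 in N4 against T4, from -0.09, 0 and -0.20 with TMM, and beside the oxidative phosphorylation median it turns those of nonsense-mediated decay (-0.42), ribosome biogenesis (-0.36) and cytokine receptors (-0.13) in N4 against naive. The count was 6624 with the DESeq2 Wald test, 4257 with no filter, 1791 with a minimum fold change of 1.5 and 1044 in a fit of only these groups. It was 959 without N4 replicate 1, 639 without N4 replicate 2, 1393 and 1278 without T4 replicate 1 or 2, and 4487 without naive replicate 2. Of the 93 called genes that the naming rule covers, 46 kept their call without N4 replicate 1, 39 without N4 replicate 2, 69 and 65 without T4 replicate 1 or 2, and 85 and 90 without naive replicate 1 or 2.

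**Figure D2:**
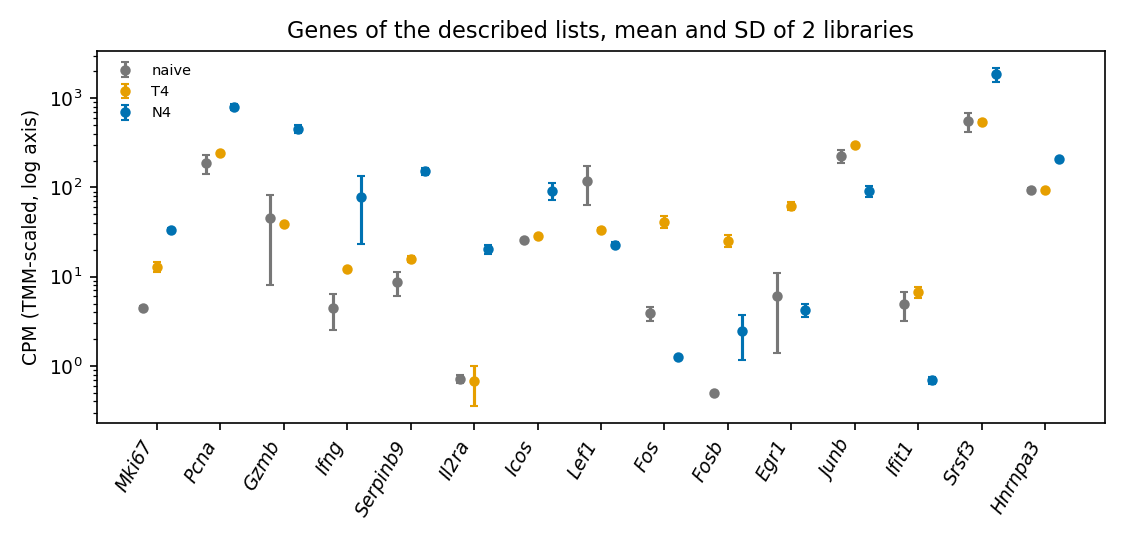
Mean CPM and SD (n = 2, log axis) of 15 genes from the described lists in naive, T4 and N4 cells. Mki67 stands at 4.49, 13 and 33.7 CPM in naive, T4 and N4 cells, and Fos at 3.89, 41.4 and 1.25 CPM.

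The comparison of T4 with naive cells asks what differed 4 days after the weaker peptide with the same antibodies, which cannot be told apart here. Fosb, an immediate early gene of the kind that responds within minutes to receptor signals or stress, had the largest increase among the called genes that the naming rule covers. It rose 50.9-fold, from 0.498 ± 0.00164 to 25.4 ± 3.94 CPM (SD, n = 2, log2 fold change 5.67, SE 0.49, edgeR adjusted p = 0.047), and the related gene Fos rose 10.6-fold to 41.4 ± 6.09 CPM (SE 0.28, adjusted p = 0.047). They were the 2 called of 25 antigen receptor response genes (7 higher and 0 lower adjusted over the list alone), whose median was 0.63 (camera adjusted p = 5e-04, and adjusted p = 0.4 with an estimated correlation, fry adjusted p = 0.054). Jun stood at 133.5 ± 2.32 CPM against 4.9 ± 4.18 (adjusted p = 0.076) and Egr1 at 61.7 ± 6.11 against 6.14 ± 4.75 (adjusted p = 0.099). Zbtb32 rose 33.5-fold to 30.1 ± 3.29 CPM, the heat shock gene Hspa1b 27-fold to 75.3 ± 1.46 CPM, and the histone genes Hist1h1d, Hist1h2bq and Hist1h2br 14.5-fold, 13.7-fold and 12.6-fold (adjusted p = 0.047). Hspa1b and the H2b genes have near-identical copies. The libraries hold polyadenylated RNA, so histone values cover only transcripts with a poly(A) tail. Cd302, Hfe, Actn2, Tmem108, Aif1, a macrophage gene, and the glucocorticoid-induced Tsc22d3 fell, with log2 fold changes of -4.23, -4.01, -3.69, -3.13, -2.73 and -2.63 (adjusted p = 0.047 to 0.049). None of these gene calls held in edgeR without any 1 of the N4 or T4 libraries. Macrophage and neutrophil markers were also lower in T4 than in naive libraries, so the decreases cannot be assigned to CD8 T cells alone.

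The cell cycle list was higher as a group in T4 than in naive cells: its median log2 fold change was 1.25 and all 35 genes had a positive value, though 0 of them passed over all genes (24 rose and 0 fell adjusted over the list alone, camera adjusted p = 4.6e-12, and adjusted p = 0.27 with an estimated correlation). Mki67 stood at 13 ± 1.57 CPM in T4 (edgeR adjusted p = 0.076). Genes of erythroid precursors, a dividing cell type, were chosen as a list after seeing the data and also had a positive median of 0.78 here, with 9 of 11 values positive and 0 called (camera adjusted p = 0.0022, and adjusted p = 0.22 with an estimated correlation). They summed to 949.5 ± 77.9 CPM in T4 and 535.4 ± 48.9 in naive libraries. Type I interferon genes had a median of 0.75 with 0 of 20 called (3 and 0 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation), with Oas1a at 20.3 ± 1 CPM against 7.9 ± 1.19. The 24 naive and memory genes had a median of -0.91 with 0 called (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.69 with an estimated correlation), with the interleukin 7 receptor gene Il7r at 14.5 ± 0.92 CPM against 60.7 ± 7.12. The interferon call ended without T4 replicate 1 (adjusted p = 0.098) and without naive replicate 1 (adjusted p = 0.16), and the naive and memory call without naive replicate 1 (adjusted p = 0.57) and with fry (adjusted p = 0.3).

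The other pathway lists did not pass the camera test in T4 against naive, and 0 of their genes passed the gene test. Counts in parentheses are those adjusted over the list alone, higher and lower. The adjusted p was 0.49 for 20 cytotoxic genes (0 and 0, median -0.01, mean 0.28) and 0.29 for 18 effector differentiation genes (0 and 0, median -0.51). It was 0.23 for 17 inhibitory receptor genes (5 and 1, median 0.3) and 0.29 for 13 costimulatory receptor genes (2 and 2, median -0.33). The value was 0.73 for 13 SR and TRA2 factors (0 and 0, median -0.02, mean 0.08) and 0.83 for 24 hnRNP and PTB factors (0 and 0, median -0.08, mean 0.01). It was 0.71 for 8 SR protein kinases (0 and 0, median 0.08, mean -0.06) and 0.55 for 15 nonsense-mediated decay genes (0 and 0, median 0.13). It was 0.28 for 20 glycolysis entries (1 and 1, median 0.42) and 0.77 for 29 oxidative phosphorylation genes (0 and 0, median 0). For 22 ribosome biogenesis genes it was 0.23 (0 and 0, median 0.29) and for 18 sterol and fatty acid synthesis genes 0.17 (0 and 0, median 0.41). It was 0.28 for 15 homing genes (2 and 5, median -0.27) and 0.28 for 17 cytokine receptor genes (0 and 2, median -0.18). Library size scaling moved the medians of the cytotoxic, SR and TRA2, hnRNP and cytokine receptor lists to 0.43, 0.39, 0.21 and 0.08. Gzmb stood at 38.9 ± 0.707 CPM in T4 and 45.5 ± 37.4 in naive libraries, and Cxcr6, a chemokine receptor gene of tissue-homing T cells, at 16.8 ± 0.909 against 101.5 ± 23.7 CPM (edgeR adjusted p = 0.062). The cytotoxic list summed to 7271.2 and 19233.3 CPM in the naive libraries and to 9333.7 ± 784.3 in T4. Natural killer cell markers stood at 176.9 ± 67.8 CPM in naive and 61.9 ± 0.9 in T4 libraries. The cytotoxic values therefore cannot be assigned to CD8 T cells alone.

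Markers of myeloid and natural killer cells were also lower as groups in T4 than in naive libraries, with 0 genes called one by one. Macrophage and monocyte markers summed to 266.1 ± 9.6 CPM in T4 (11 lower adjusted over the list alone, median -5.27, camera adjusted p = 4.4e-11, and adjusted p = 0.14 with an estimated correlation). Neutrophil markers summed to 7.5 ± 3.8 CPM (8 lower adjusted over the list alone, median -10.26, adjusted p = 2.4e-09, and adjusted p = 0.27 with an estimated correlation). Dendritic cell markers summed to 561 ± 11.9 CPM against 1717.5 ± 543.2 (5 lower adjusted over the list alone, median -1.36, adjusted p = 0.022, and adjusted p = 0.46 with an estimated correlation). That call ended without naive replicate 1 (adjusted p = 0.26), without naive replicate 2 (adjusted p = 0.064) and with fry (adjusted p = 0.084). Natural killer cell markers summed to 61.9 ± 0.9 against 176.9 ± 67.8 CPM (4 lower adjusted over the list alone, median -1.35, adjusted p = 0.0022, and adjusted p = 0.27 with an estimated correlation). B cell markers were at 158.3 ± 16.2 CPM in T4 and 191.3 ± 52.8 in naive libraries (0 adjusted over the list alone, median 0.21, adjusted p = 0.29). That list holds the immunoglobulin gene Ighd but not Igkc. Immunoglobulin genes together held 0.107% and 0.097% of the counts in T4 but 0.527% in naive replicate 1 and 5.374% in naive replicate 2. In the latter library Igkc was the gene with the most counts. Red cell markers were at 7317.4 ± 1141 and 6339.8 ± 4090.8 CPM (0 adjusted over the list alone, median 0.21, adjusted p = 0.49). CD4 and regulatory T cell markers summed to 1.2 ± 0.4 against 4.2 ± 1.1 CPM (1 lower adjusted over the list alone, median -1.43, adjusted p = 0.16). Stromal and endothelial markers summed to 10.9 ± 1.5 against 10.5 ± 0.8 CPM (0 adjusted over the list alone, median -1.14, adjusted p = 0.71).

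In all, 27 of 23003 genes passed in T4 against naive, 19 higher and 8 lower, with a lowest adjusted p of 0.047, while 3329 genes had an unadjusted p under 0.05. The count was 0 with DESeq2 size factors (3360 at an unadjusted p under 0.05), 0 in a fit of only these groups (3531), 0 with a minimum fold change of 1.5 (2464). It rose to 53 under library size scaling, 330 with a stricter filter, 956 with no filter and 2241 with the DESeq2 Wald test. It was 0 without N4 replicate 1 or 2 and without T4 replicate 1 or 2 (3313, 3308, 1577 and 1631 at an unadjusted p under 0.05), 357 without naive replicate 1 and 317 without naive replicate 2. It was also 157 with a length correction and 237 with counts divided by 4.

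The comparison of N4 with T4 cells sets the peptides against each other. Some cell cycle and cytotoxic genes were called higher in N4 cells, and some immediate early and interferon genes higher in T4 cells. Of 35 cell cycle genes 9 were called, all higher in N4 (15 adjusted over the list alone, median 0.93, or 0.06 under library size scaling, camera adjusted p = 2.4e-07, and adjusted p = 0.23 with an estimated correlation). The replication clamp gene Pcna stood at 798.7 ± 66 CPM in N4 and 242.7 ± 2.25 in T4 (SD, n = 2, log2 fold change 1.72, SE 0.27, edgeR adjusted p = 0.028). Of 20 cytotoxic genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone, median 1.06, or 0.2 under library size scaling, camera adjusted p = 0.032, and adjusted p = 0.52 with an estimated correlation). Gzmb was 11.7-fold and Serpinb9 9.73-fold higher in N4 (adjusted p = 0.034 and 0.014). Of 25 antigen receptor response genes 6 were lower in N4 (7 adjusted over the list alone, median -0.8, camera adjusted p = 0.0081, and adjusted p = 0.3 with an estimated correlation). The log2 fold change was -5.04 for Fos (SE 0.31, adjusted p = 0.013), -3.99 for Dusp1, -3.86 for Egr1, -3.38 for Fosb, -3.31 for Jun and -1.69 for Junb. Of 20 type I interferon genes 7 were lower in N4 (12 adjusted over the list alone, median -1, camera adjusted p = 2e-04, and adjusted p = 0.23 with an estimated correlation). Library size scaling moved the medians of the antigen receptor and interferon lists to -1.63 and -1.88. Ifit1 stood at 0.687 ± 0.0663 CPM in N4 and 6.74 ± 0.902 in T4 (adjusted p = 0.022). None of these gene calls held in edgeR without N4 replicate 2 or without T4 replicate 2, where the count of calls was 0.

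Some splicing factors and metabolic genes, a minority in each list, were called higher in N4 than in T4 with TMM, and library size scaling turned the median of each of these lists below 0. Of 24 hnRNP and PTB factors 7 were higher (9 adjusted over the list alone), with a median of 0.71, or -0.15 under library size scaling (camera adjusted p = 8.4e-06, and adjusted p = 0.23 with an estimated correlation). Hnrnpa0 was 3.85-fold higher, Ptbp2 2.94-fold and Hnrnph2 2.61-fold (edgeR adjusted p = 0.026, 0.037 and 0.03). Of 13 SR and TRA2 factors 1 was higher (3 adjusted over the list alone), Srsf3 at 1855 ± 345 CPM in N4 and 543.5 ± 24.2 in T4. The list's median was 0.58, or -0.28 under library size scaling (camera adjusted p = 0.013, adjusted p = 0.23 with an estimated correlation, and adjusted p = 0.12 with a GC correction, where the median fell to 0.14). Oxidative phosphorylation had 2 of 29 genes higher (7 adjusted over the list alone, median 0.57 or -0.3, camera adjusted p = 0.0037, and adjusted p = 0.3 with an estimated correlation), among them the cytochrome c gene Cycs. Sterol and fatty acid synthesis had 1 of 18 higher, Idi1 (1 adjusted over the list alone, median 0.65 or -0.2, camera adjusted p = 0.033, and adjusted p = 0.25 with an estimated correlation). Glycolysis had 1 of 20 higher, Pgk1 (1 adjusted over the list alone, median 0.29 or -0.53, camera adjusted p = 0.033, and adjusted p = 0.5 with an estimated correlation). Without N4 replicate 1 the cytotoxic (adjusted p = 0.11), glycolysis (0.19) and sterol (0.12) calls ended. Without N4 replicate 2 the antigen receptor call ended (0.08), and without T4 replicate 2 the glycolysis call (0.062), while fry ended the cytotoxic (0.21) and glycolysis (0.34) calls.

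Among called genes that pass the naming rule's filters (a mean log2 CPM of at least 3 among them), the largest increases from T4 to N4 were those of Mt3 (91.2-fold), AA467197 (58.7-fold), the phosphatase gene Ptprk (38.6-fold), Ly6a, a surface marker of activated T cells that rose 25.3-fold to 6907 ± 1810 CPM, Nebl (17.7-fold) and S100a4 (17.2-fold to 4072 ± 954 CPM), with edgeR adjusted p = 0.013 to 0.039. The largest decreases among them were those of Cd209a, a dendritic cell lectin gene (log2 fold change -7.45), Apoe (-6.70), Lrg1 (-5.96), Ctsh (-5.88), the red cell antigen gene Rhd (-5.59) and Prss50 (-5.49), with adjusted p = 0.019 to 0.045. Lrg1 stood at 0.0098 ± 0.0138 CPM in N4 and 0.614 ± 0.165 in T4, so the size of its fold is uncertain. Markers of dendritic cells, red cells and macrophages were lower in N4 too, so these decreases cannot be assigned to CD8 T cells alone. Il2ra was 29.7-fold higher in N4, and Cxcr6 15.5-fold (adjusted p = 0.014 and 0.013).

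Lists without a camera call in N4 against T4 follow, with counts adjusted over the list alone in parentheses. Of 18 effector differentiation genes 3 were higher and 2 lower (5 and 2, median 0.6, camera adjusted p = 0.12), with Id2, a transcription regulator of effector cells, 6.27-fold higher. Of 24 naive and memory genes 3 were lower (0 and 3, median -0.64, adjusted p = 0.068), among them Id3 and Myb. Of 17 inhibitory receptor genes 2 were higher (2 and 2, median -0.05, mean 0.02, adjusted p = 0.73), Cd244a and Havcr2. Of 13 costimulatory receptor genes 2 were higher (4 and 1, median 0.47, adjusted p = 0.16), Cd226 and Icos. Of 15 homing genes 1 was higher (1 and 0, median 0.28, adjusted p = 0.063), and of 17 cytokine receptor genes 2 were higher and 1 lower (3 and 3, median 0.56, adjusted p = 0.28). Of 15 nonsense-mediated decay genes 1 was higher, Magoh (2 and 0, median -0.02, mean 0.16, adjusted p = 0.4). Neither 8 SR protein kinases (0 and 0, median -0.2, adjusted p = 0.84) nor 22 ribosome biogenesis genes (0 and 0, median 0.06, mean -0.06, adjusted p = 0.73) had a called member. Library size scaling turned the positive medians among these below 0: effector differentiation to -0.27, costimulatory receptors to -0.34, homing to -0.54, cytokine receptors to -0.29 and ribosome biogenesis to -0.77.

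**Figure D3:**
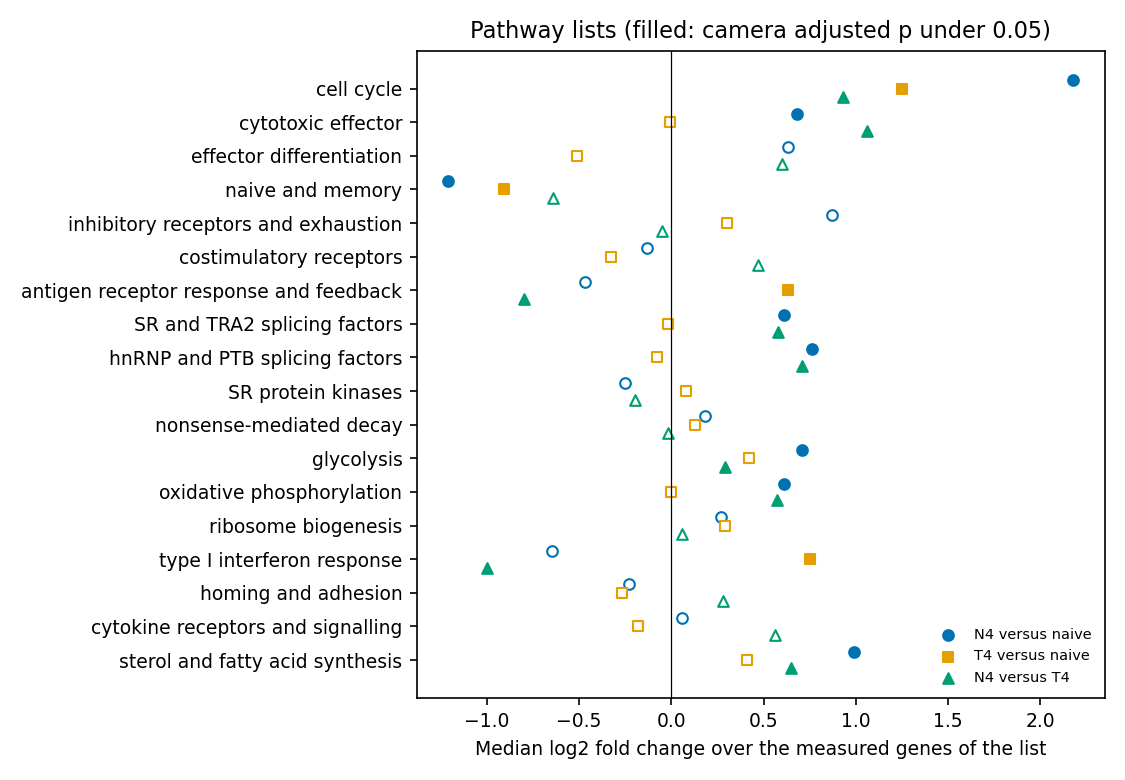
Median log2 fold change (TMM) over the measured genes of each pathway list in the 3 comparisons, with filled symbols for a camera adjusted p under 0.05. The cell cycle list lies at 2.18, 1.25 and 0.93, and under library size scaling the N4 against T4 medians of the splicing, glycolysis, oxidative phosphorylation and sterol lists turn below 0.

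Markers of other cells were lower in N4 than in T4 beside these groups. Of 7 red cell markers 5 were lower (7 adjusted over the list alone, median -4.35, camera adjusted p = 3.7e-05, and adjusted p = 0.3 with an estimated correlation). Of 11 B cell markers 6 were lower (9 adjusted over the list alone, median -3.7, or -2.88 with bounds, adjusted p = 4.8e-06, and adjusted p = 0.23 with an estimated correlation). Of 12 macrophage and monocyte markers 5 were lower (6 adjusted over the list alone, median -2.7, adjusted p = 0.0028, and adjusted p = 0.23 with an estimated correlation), with Lyz2 at 12 ± 0.509 CPM in N4 and 236.4 ± 8.92 in T4. Of 10 dendritic cell markers 4 were lower (6 adjusted over the list alone, median -2.75, adjusted p = 0.0037, and adjusted p = 0.25 with an estimated correlation). Of 6 natural killer cell markers 3 were lower (4 adjusted over the list alone, median -3.31, adjusted p = 0.01, and adjusted p = 0.23 with an estimated correlation). Neutrophil markers had 0 of 8 called (0 adjusted over the list alone, median 1.78, adjusted p = 0.17), CD4 and regulatory T cell markers 0 of 4 (0 adjusted over the list alone, median 1.37, mean -0.14, adjusted p = 0.24), and stromal and endothelial markers 1 of 8, lower (2 adjusted over the list alone, median -1.83, or -1.15 with bounds, adjusted p = 0.12).

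**Figure D4:**
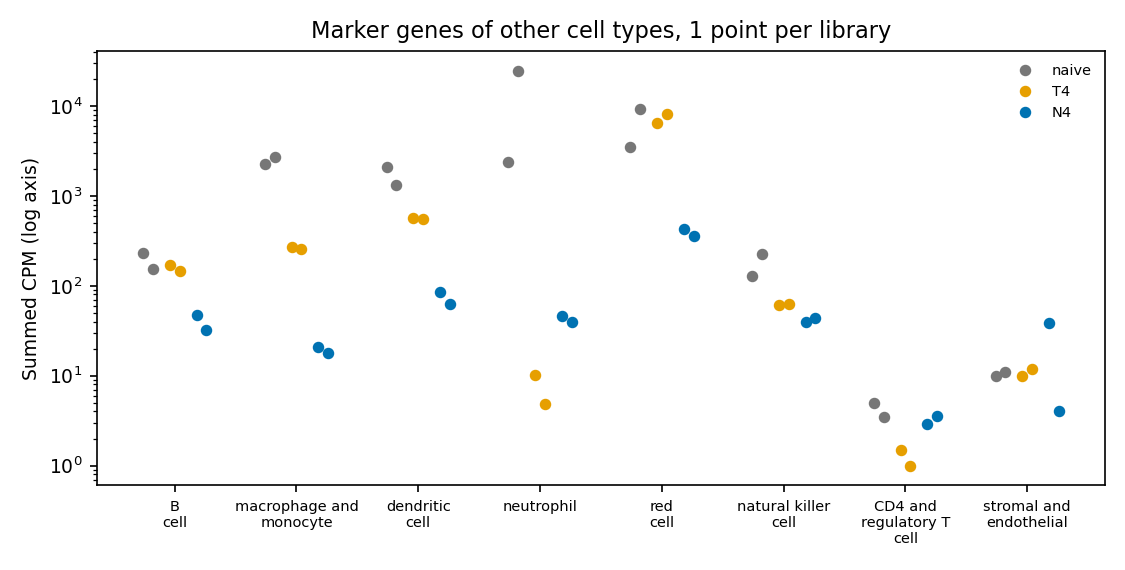
Summed CPM (log axis) of markers of other cell types, per library and group. Neutrophil markers stand at 2394 and 24753.4 CPM in the naive libraries and at a mean of 7.5 CPM in T4 libraries, and macrophage markers at means of 2468.6, 266.1 and 19.2 CPM in naive, T4 and N4 libraries.

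In all, 1830 of 23003 genes passed in N4 against T4, 801 higher and 1029 lower (6727 at an unadjusted p under 0.05). Under library size scaling 320 were higher and 1736 lower. The count was 295 without N4 replicate 1 and 45 without T4 replicate 1. It was 0 without N4 replicate 2 and 0 without T4 replicate 2 in edgeR's quasi-likelihood test (4752 and 3818 at an unadjusted p under 0.05), while it was 4437 and 4547 without naive replicate 1 or 2. It was 6206 with the DESeq2 Wald test, 3834 with no filter, 3113 with a stricter filter, 5281 in a fit of only these groups, 2812 with counts divided by 4, 1145 with a GC correction and 769 with a minimum fold change of 1.5. Of the 73 called genes that the naming rule covers, 23 kept their call without N4 replicate 1 and 6 without T4 replicate 1.

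With an estimated correlation, camera called 0 of the 26 lists in each comparison (6, 4 and 5 at an unadjusted p under 0.05 in N4 against naive, T4 against naive and N4 against T4), while the preset correlation called 14, 8 and 14 and fry 15, 6 and 15. Lists with an estimated correlation below the preset 0.01 lost their call too. Macrophage markers (-0.03) and SR and TRA2 factors (-0.01) did so in N4 against naive. Correlation between genes alone therefore does not account for the lost calls, and that setting also uses only the 3 residual degrees of freedom.

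Both responses against naive were then set side by side. Across 23003 genes their log2 fold changes correlated at r = 0.55 with a covariance of 4.18, and genes are not independent replicates. Both share the naive libraries, and simulated unchanged groups against those libraries gave a mean r of 0.15 (highest 0.16) and a covariance of 0.18, so the covariance exceeded the simulated one by 4. Sharing these controls makes the changes correlate even without a response. The simulations may not carry the full spread between the naive libraries (r = 0.915), so the excess does not measure a shared response alone. Both comparisons also carry the antibodies and the lower markers of other cells, which the simulated groups do not. Those markers had medians of -8.09 and -10.26 for neutrophil and -7.36 and -5.27 for macrophage genes. The correlation is therefore not one of peptide responses alone. Of the genes called in both, 15 were higher, where independent lists would share 0.93 (1120 and 19 of 23003), and 8 lower, where they would share 0.57. Part of this excess may come from the shared controls, since 2 naive libraries are too few to split.

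Transcript usage changed in 84 genes in N4 against naive, 27 in T4 against naive and 108 in N4 against T4 (Simes adjusted p under the threshold, 1199, 873 and 1165 at an unadjusted p under 0.05). Klrd1, the CD94 chain of a killer cell receptor, had 20.3% ± 0.5 of its counts in its coding transcript of 919 bases in naive libraries, 0.3% in T4 and 0.1% in N4 (adjusted p = 5.2e-07 in N4 and 0.00013 in T4 against naive). Natural killer cell markers summed to 176.9 ± 67.8 CPM in naive, 61.9 ± 0.9 in T4 and 41.7 ± 3.5 in N4 libraries. A different mix of cells and a change of use within CD8 T cells therefore cannot be told apart for Klrd1. Hnrnpul1, which encodes an hnRNP-like protein, was also called. Its coding transcript Hnrnpul1-201 made up 41.7% ± 4.5 of its counts in T4 and 39.4% ± 1.2 in naive cells and had 0 counts in N4 (adjusted p = 0.0085 against naive and 0.007 against T4). Lef1-201, a coding transcript of the transcription factor gene Lef1, had a share of 21% ± 1.6 in T4 and 7.9% ± 2.1 in naive cells and 0 in N4 (adjusted p = 0.00011 in N4 against T4). Mbnl1-218, from the splicing regulator gene Mbnl1, took 19.3% ± 3.3 in T4, 20.2% ± 28.5 in naive cells and 0 in N4 (adjusted p = 2e-04 in N4 against naive). The other genes of smallest p were Sec11c, Dtx3 and D16Ertd472e in N4 against naive. In T4 against naive they were Sec11c, Esd, Metap2 and Ankrd37, and in N4 against T4 Esd, Ankrd37, Dtx3 and Mbnl1. The decay transcript of Ankrd37 of 884 bases made up 30.4% ± 4.6 in N4, 11.5% ± 1.6 in naive and 0 in T4 cells. Many of these transcripts were at 0 in one group, where an estimate that assigns reads to a related transcript instead would also give 0. The counts fell to 24 and 23 in N4 against naive without N4 replicate 2 or T4 replicate 1 and to 27 without T4 replicate 2. They fell to 2 and 6 in T4 against naive without T4 replicate 1 or 2, and to 54, 26, 8 and 27 in N4 against T4 without N4 replicate 1 or 2 or T4 replicate 1 or 2.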

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

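The library size scaling, length correction, GC correction and division of counts by 4 were chosen after seeing the data. The other alternatives were set before the data were examined. In the order N4 against naive, T4 against naive and N4 against T4, the counts of changed genes (2772, 27 and 1830) became 6624, 2241 and 6206 with the DESeq2 Wald test, and 4257, 956 and 3834 with no filter. They became 1044, 0 and 5281 with only the 2 groups compared, and 1791, 0 and 769 with a minimum fold change of 1.5. DESeq2 size factors gave 0 for T4 against naive, and the stricter filter gave 330 there and 3113 in N4 against T4. A replicate block, for which the replicate numbers carry no pairing (correlations of replicate deviations between groups 0.017, 0.080 and 0.037), gave 130 in T4 against naive and 3367 in N4 against T4. Among the added alternatives, T4 against naive moved to 157 with a length correction, 53 under library size scaling and 237 with counts divided by 4, and N4 against T4 to 1145 with a GC correction and 2812 with counts divided by 4. With each library left out in turn the counts ranged from 639 to 4487, from 0 to 357 and from 0 to 4547, the lone library of a group being assumed to vary like the others. Where edgeR's count was 0 without a library, between 1577 and 4752 genes had an unadjusted p under 0.05. For Tra2b in N4 against T4 the log2 fold change of 0.41 reversed to -0.057 with a GC correction and to -0.458 under library size scaling, neither past the threshold (adjusted p = 0.91 and 0.335). The gene lists called by camera (14, 8 and 14 of 26) became 0, 0 and 0 with an estimated correlation, and ranged from 13 to 17, 5 to 9 and 12 to 15 with libraries left out. The correlation of both responses against naive (0.55) was 0.651 over genes with a mean log2 CPM of at least 3 and 0.488 to 0.624 with libraries left out. Genes with changed transcript usage (84, 27 and 108) became 390, 85 and 309 with the gene-level F test and 34, 12 and 40 with the replicate block, while the stricter filter gave 136 and 43 in the comparisons with naive. They ranged from 23 to 115, 2 to 40 and 8 to 153 with libraries left out. The Tra2b poison exon share difference kept its direction with each library left out: -9.7 to -6.3, 4.1 to 8.1 and -16.1 to -12.1 points. The median decay transcript share of SR and TRA2 factors was -2.84 and -3.32 points when divided by length in N4 against naive and N4 against T4, and ranged from -1.7 to -0.69, from -0.69 to 0.03 and from -1.8 to -0.22 points with libraries left out, so that its sign in T4 against naive rests on single libraries. For each of these changes the cause was not tested.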

Other observations

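All tests in this part were chosen after the results were seen, and so were the lists of erythroid precursor, histone, CD8 identity and heat shock genes. Standard errors of medians in this part come from 500 resamplings of the genes. They hold no spread between libraries, so statements based on them are limited to these libraries. The lower Tra2b poison exon share in N4 than in T4 libraries could come from transcript coverage that favours shorter transcripts in 1 group. Over 689 other genes with a similar length ratio of their main transcripts, the share of the shorter transcript differed by a median of -0.25 points (SE 0.44) in N4 minus T4, which argues against it in these libraries. A general shift of decay transcripts stays open: 164 other genes with 20% to 60% of their counts in decay transcripts had a median difference of -7.96 points (SE 2.28), against -13.4 points for the decay transcripts of Tra2b. Chance spread stays open too, since the share of 45.7% of those genes differed between N4 and T4 by at least as much. Those genes were noisier than Tra2b, with median differences between replicates of 12.7, 8.8 and 10.7 points in N4, T4 and naive libraries against 3.8, 3.5 and 2.7 for Tra2b, so 45.7% may overstate what chance gives for a gene as steady as Tra2b. Both tests were first run over 1626 genes with decay transcripts at a log2 CPM of at least 3, where the median difference was -0.04 points and Tra2b lay at percentile 6.4. They were replaced by the genes above because a share near 0 cannot move as far, and the choice of genes changed the outcome for the general shift, while chance spread stayed open with either choice. A lower share of nuclear or unspliced RNA in N4 libraries stays open as well, given their lower Malat1 and retained intron shares, and so does a difference in splicing between the peptides, as an untested hypothesis.

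Transcripts of other cell types differed between the groups and between the naive libraries. A lower share of CD8 T cells with the other types in fixed proportion would move their markers alike, whereas from naive to T4 B cell and macrophage markers moved apart by 2.96 log2 units (SD 0.47), which argues against it. Red cell markers changed by 0.37 (SD 1.03), against -3.21 (SD 0.19) for macrophage markers. Immunoglobulin did fall, with Igkc at 1587.5 and 34589.9 CPM in naive and 269.2 and 253.5 CPM in T4 libraries, so transcripts of the B lineage did not move as 1 group. Neutrophils in naive replicate 2 may explain its high neutrophil markers: 6 of the 8 markers were over 1.5 times higher there than in naive replicate 1, S100a8 by 10.4-fold and Camp by 19.8-fold. Mmp9 (1.29-fold) and Csf3r (1.19-fold) were not, and mature neutrophils carry these too, so neutrophils and another source cannot be told apart. Erythroid precursor genes summed to 57.6 ± 7.1 CPM in N4, 949.5 ± 77.9 in T4 and 535.4 ± 48.9 in naive libraries (SD, n = 2). Their median log2 fold change was -3.24 in N4 against naive, 0.78 in T4 against naive and -4.08 in N4 against T4, with camera adjusted p = 6.8e-07, 0.0022 and 1.2e-07, and adjusted p = 0.083, 0.22 and 0.066 with an estimated correlation. The CD8 identity genes summed to 4211.6 ± 634.4, 3598.8 ± 127.5 and 5038.3 ± 13.2 CPM, with medians of -0.89, -0.24 and -0.72 (camera adjusted p = 0.12, 0.32 and 0.62). Cd3d alone gave 2580, 1470 and 2310 CPM of these sums in N4, T4 and naive libraries. In the same order Cd8b1 stood at 175 ± 16.4, 424 ± 11.7 and 512 ± 270 CPM and Cd8a at 78.3 ± 8.63, 109 ± 7.2 and 145 ± 54.6. In N4 against naive 8 of 9 members had a negative log2 fold change, and only Lat was called (edgeR adjusted p = 0.047). A contribution of female cells that differs between libraries stays open and untested: Xist was at 20.3 and 31.5 CPM in naive, 7.09 CPM in N4 replicate 2 and 0.05 CPM or less in the other libraries, while Ddx3y of the Y chromosome was at 4.41 CPM or more in all 6.

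Immediate early transcripts were higher in T4 than in N4 libraries. A stress response to handling of the T4 cells predicts higher heat shock genes, whose median log2 fold change (T4 over N4) was 0.09 (SE 0.37, 8 of 14 higher in T4), and Hspa1b stood at 75.3 CPM in T4 and 10.1 in N4. The 3 called members were all higher in T4: Hspa1b, Hspa1a and Hspb1 (edgeR adjusted p = 0.025, 0.031 and 0.034). Hspb1 was near the floor, at 0.456 CPM in T4 and 0 in N4. The uncalled members went both ways, and 6 of the 14 were higher in N4. The list as a whole thus decides nothing, so handling and receptor signalling cannot be told apart. Transcripts of macrophages, neutrophils and dendritic cells could be the source, but naive libraries hold more of the markers of these cells than T4 libraries. The 6 immediate early genes had a median log2 fold change of 3.37 (SE 1.17) in T4 over naive libraries, which argues against these cells, at the state they have in naive libraries, as the source for the group as a whole. Single values were 5.67 for Fosb, 4.77 (SE 0.72) for Jun, 3.41 for Fos and 3.33 (SE 0.60) for Egr1, of which Fosb and Fos passed the threshold (adjusted p = 0.047) and Jun and Egr1 did not (0.076 and 0.099). That source stays open for Dusp1 (0.94, adjusted p = 0.53) and Junb (0.39, adjusted p = 0.55). The genes were picked from the same T4 libraries, which can raise the median. Erythroid precursors and B cells were not tested as a source of the immediate early transcripts. Their markers too were higher in T4 than in N4, at 949.5 against 57.6 CPM and at 158.3 against 40.1 CPM. Replication histone genes summed to 2306.5 ± 525.4 CPM in N4, 958.1 ± 79.8 in T4 and 353.9 ± 198.1 in naive libraries. Their medians were 2.82, 2.41 and -0.24 in N4 against naive, T4 against naive and N4 against T4 (camera adjusted p = 6.9e-10, 1.7e-11 and 0.62, and adjusted p = 0.3, 0.22 and 0.87 with an estimated correlation), and many are near-identical copies. These values cover only histone transcripts with a poly(A) tail. The heat shock list summed to 2863 ± 213.3, 1763.9 ± 34.3 and 1476.7 ± 478.1 CPM, with medians of 0.77, 0.46 and -0.09 (camera adjusted p = 0.07, 0.0091 and 0.62, and adjusted p = 0.38, 0.22 and 0.87 with an estimated correlation).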
